A study of Mus musculus with 6 samples.

How the data were processed

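Total RNA of double-negative thymocytes, the T cell precursors that carry neither CD4 nor CD8, was measured on 6 single-colour Affymetrix mouse expression arrays. Per the labels, 3 arrays came from RAG1-deficient mice and 3 from RAG1/Ezh2 double mutant mice. Each sample was put in its group from its description. The labels do not say whether the samples of a group came from separate animals. The p-values of single probe sets and measures therefore cover only the spread between these samples, which may be technical. The labels also do not say which part of Rag1 or Ezh2 was missing, nor the mouse strain, sex or age.

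The deposited table holds 1 linear intensity for each of 12488 probe sets on each array. The software that made the values and its settings are not given in the sources used here. Read from the values, every deposited intensity was above 0, with 0.1 as the lowest, and the 2%-trimmed mean lay between 500.293 and 500.37 on all 6 arrays, so each array had been scaled to 1 common mean before deposit. Such scaling sets the average of each array equal and would hide a change shared by most transcripts. No detection calls and no background level were used here, and the number of arrays limits the precision. An Affymetrix array of this type probes transcripts mostly near their 3' ends, and a probe set's intensity cannot be set against that of another probe set.

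The 66 control probe sets stayed out of the tests, which left 12422. Gene names came from the platform's probe table, with symbols looked up through the Entrez gene number in a RefSeq table of assembly GRCm38.p6, which was used only for names and for the order of neighbouring genes. This match found 10839 probe sets and changed 0 symbols. A single gene was named for 10833 probe sets, several for 396 and none for 1193; a probe set with several genes or none was not named. Probe sets whose identifier ends in _f_at or _s_at can detect several related transcripts.

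Values were tested as log2(intensity + 23), where 23 is the 20th percentile of all values rounded to a whole number, and every log2 difference is on this scale, which understates the change of dim probe sets. The deposited scaling was kept because the trimmed means differed by less than the limit set for this choice. Probe sets above an intensity of 86.5, the 40th percentile of all values, on at least 3 of the 6 arrays were tested, whichever arrays these were. This left 7642 probe sets of 5751 named genes. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean level), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Differences are given as the double mutant minus the RAG1-deficient group. Standard errors (SE) are those of the unpaired fit. Single measures such as RNA quality were compared with an exact two-sided permutation test of the group means, whose smallest possible p with 3 arrays against 3 is 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

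The sample titles come in 3 styles, called here numbered, Rag and Thy after their wording, and each style holds 1 array of each group. The replicate numbers used here name arrays only: number 1 has the numbered style, number 2 the Rag style and number 3 the Thy style in both groups. The titles of the numbered and Thy arrays contain DN, whereas both Rag titles name T cells and contain neither DN nor Thy. The titles therefore give the double-negative stage for the numbered and Thy arrays only. The titles of RAG1-deficient replicates 1 and 3 end in WT, although their descriptions name RAG1. The labels do not say what WT refers to. Whether the styles pair the arrays was checked before any calls were compared. The deviations from the group means, taken across genes, correlated between the 2 arrays of a style at 0.570 for the numbered style, 0.736 for the Rag style and 0.602 for the Thy style, while correlations between arrays of different styles lay between -0.635 and 0.0394. Deviations cancel out within a group, which pushes the correlations between different styles towards negative values, so their range is no independent baseline. The first principal component, with 47.5% of the variance, set the Rag arrays apart from the other 4. All 3 styles exceeded the limit of 0.1 set for pairing, so the fit with title style as a block (the paired fit) is given beside the fit with group alone (the unpaired fit) where it changes a call. The pairing is read from the titles and the data; no label states a shared litter, day or batch.

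The 18 gene lists were fixed in advance: Polycomb group, developmental regulators marked by H3K27me3 in many cell types, CDK inhibitors and p53 response, cell cycle, early thymocyte, beta-selection and double-positive stage, T cell receptor signalling and actin cytoskeleton, gamma-delta T cells, immediate early and stress genes, interferon response, glycolysis and hypoxia, sex-linked genes, and markers of B lineage, myeloid, antigen-presenting, NK and innate lymphoid, erythroid and stromal cells. Each was tested with limma's camera with a preset inter-gene correlation of 0.01, with the brightest probe set for each gene, two-sided and adjusted over the lists with at least 3 tested members. Camera sets the genes of a list against the other genes. With this preset correlation its p-value does not measure how the list varied between samples. The genes named were also fixed by a rule in advance: Ezh2, Ezh1, Eed, Suz12, Rag1 and Rag2 whatever their values; the 12 largest changes in each direction among probe sets that passed without overlap between the groups, filled up to 12 with the non-overlapping probe sets of smallest unadjusted p, said not to have passed; and up to 4 members of each list with the smallest unadjusted p. Where a named gene has several tested probe sets, the value is that of the smallest unadjusted p unless said otherwise. Adjustment over a list alone used the brightest probe set of each gene, which can be another one. Genes named outside this rule are said to be so where they appear.

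The fits were tested on simulated data of 7642 probe sets with the spread of the paired fit and the offsets between title styles, with 200 probe sets changed, over 20 runs. At a log2 change of 1 the unpaired fit recovered 3.6% and the paired fit 80.6%; at 2 these were 66.2% and 99.4%, and at 4 they were 94.5% and 100%. Of the calls, 0.0788% were false in the unpaired and 7.36% in the paired fit, and the paired figure rests on a simulation in which the pairs are real.

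The alternatives chosen before the data were examined were quantile, cyclic loess and median scaling, other pseudocounts (1 and 86.5), a floor in place of the pseudocount, no filter and a filter at the 60th percentile, no variance trend, array weights, the title-style block, leaving out each array, other thresholds (adjusted p under 0.1, and a fold of at least 2), and for the lists an estimated correlation, limma's fry and the mean of all probe sets of a gene. Combinations of the block with these, and the block without each pair, were added after the data had been seen. Probe sets at or under the filter were not tested, and the control probe sets were used only for RNA quality.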

Results

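Transcript levels were measured in double-negative thymocytes of RAG1-deficient mice (3 arrays) and of RAG1/Ezh2 double mutant mice (3 arrays). RAG1 is part of the recombinase that assembles antigen receptor genes, and thymocytes without it stay at the double-negative stage. Ezh2 is the histone methyltransferase of Polycomb repressive complex 2, which places the repressive mark H3K27me3. The comparison asks which transcripts differ when Ezh2 is missing from cells held at this stage. Between 55.2% and 64.3% of the probe sets of each array lay above the level used as a filter.

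The targeted gene came first. Ezh2 had a scaled intensity of 1622 ± 178 (SD, n = 3) in RAG1-deficient and 555 ± 231 (SD, n = 3) in double mutant thymocytes, without overlap. Its log2 difference was -1.60 ± 0.34 (SE), and it was lower in the double mutant in all 3 pairs, by a log2 difference of -2.21 in the numbered, -1.30 in the Rag and -1.28 in the Thy pair. In the unpaired limma fit Ezh2 did not pass (adjusted p = 0.332), and in the paired fit it fell (adjusted p = 0.0261). The paired call of Ezh2 ended with quantile scaling (adjusted p = 0.0517), without the filter (0.0716), without the numbered pair (0.0796) and without the Thy pair (0.111). The exact permutation p was 0.1, the smallest that 3 arrays against 3 allow. The labels do not say which exons were missing, so the remaining signal does not say how much functional transcript was left. The other core members of the complex did not pass in either fit. The log2 difference was 0.24 ± 0.22 (SE) for Eed and -0.31 ± 0.26 (SE) for Ezh1, a related methyltransferase, and lay between -0.03 and 0.15 over the 3 probe sets of Suz12. Rag1 transcript gave a bright signal in both groups, 7146 ± 185 (SD, n = 3) against 5264 ± 117 (SD, n = 3), with a log2 difference of -0.44 ± 0.19 (SE) that did not pass in either limma fit (adjusted p = 0.143 in the paired fit). A second, dimmer probe set of Rag1 showed -0.29, was higher in the Rag pair (0.57) and did not pass. Rag2 likewise did not pass, with a log2 difference of -0.35 ± 0.22 (SE).

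Bex4, Bex1 and Mt2 rose, and they were the only probe sets to pass in the unpaired fit. Bex4 and Bex1, small X-linked genes known from brain, went from 88.9 ± 32.9 (SD, n = 3) to 2484 ± 970 (SD, n = 3) and from 25.7 ± 12.8 (SD, n = 3) to 980 ± 447 (SD, n = 3). Their log2 differences were 4.46 ± 0.35 (SE) and 4.30 ± 0.40 (SE), with adjusted p of 0.00624 and 0.0126 in the unpaired limma fit. Mt2, a metal-binding metallothionein, rose from 349 ± 115 (SD, n = 3) to 2147 ± 124 (SD, n = 3), a log2 difference of 2.58 ± 0.26 (SE) with an adjusted p of 0.0126. In that fit 0 were lower, against 175 higher and 69 lower at an unadjusted p under 0.05. In the paired limma fit 43 probe sets (41 named genes) rose and 8 fell, which is 84.3% higher, and the 3 genes above were among them. At an unadjusted p under 0.05 the paired fit gave 591 higher and 413 lower. All 51 moved the same way in each of the 3 pairs, and 46 of them showed no overlap between the groups. The paired fit selects probe sets that move alike in the pairs, so this agreement is no separate support. Of all tested probe sets 7.13% had no overlap, 322 of them higher and 223 lower. Chance would give 10% only if arrays of different title styles were interchangeable. Arrays of a style deviated together, so the observed share cannot be read against that figure.

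Among the 12 named rises, 9 passed only in the paired fit. The rule chose them without overlap, so each was bound to be higher in all 3 pairs. The small GTPase Rab34 rose from 80.8 ± 50.7 (SD, n = 3) to 573 ± 177 (SD, n = 3), a log2 difference of 2.59 with an adjusted p of 0.00356 in the paired limma fit. Cenpv, a centromere protein gene, rose by a log2 difference of 2.46, the neural cell adhesion molecule Ncam1 by 2.25 and the Hippo pathway coactivator Yap1 by 2.06. The linker histone gene H1f10 rose from 176 ± 49.3 (SD, n = 3) to 759 ± 80.7 (SD, n = 3). The septin gene Septin10 rose from 51.1 ± 6.90 (SD, n = 3) to 275 ± 51.6 (SD, n = 3). The phosphatase gene Ptpn13 rose by 1.94, the mitochondrial outer membrane gene Mtx2 by 1.73, and the connexin gene Gja1, read by a probe set that can detect related transcripts, by 1.65. Adjusted p of these 8 lay between 0.0192 and 0.0261 in the paired fit. A second probe set of Ncam1 showed a log2 difference of 0.34 and did not pass (paired adjusted p = 0.688). Another, under the filter and not tested, was lower in the double mutant, at 8.0, 5.5 and 9.8 against 12.9, 30.9 and 30.8, so the rise of Ncam1 rests on 1 of 3 probe sets. Further probe sets of Cenpv, Yap1 and Gja1 lay under the filter and were not tested.

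**Figure D1:**
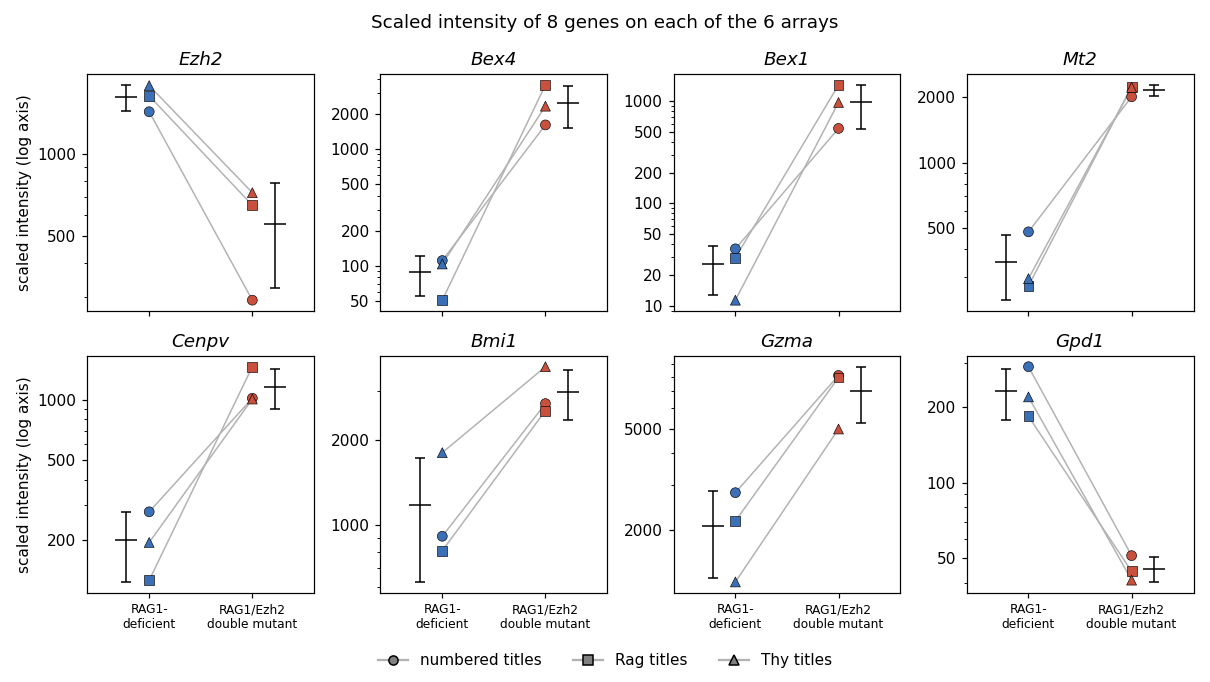
Scaled intensity (log axis) of 8 genes on each array, with RAG1-deficient arrays in blue and double mutant arrays in red; marker shapes and grey lines join the arrays whose titles share a style, and the bars beside them give the mean and SD of each group (n = 3). Ezh2 lies between 1435 and 1790 on the RAG1-deficient and between 292 and 724 on the double mutant arrays, and in all 8 genes the 3 lines run the same way. None of the 8 overlapped between the groups, so their lines were bound to do so.

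The 12 genes named as lower are those with the smallest unadjusted p among probe sets without overlap, because 0 probe sets fell in the unpaired limma fit. Of these 12, 5 fell in the paired fit. Gpd1, which encodes cytosolic glycerol phosphate dehydrogenase, fell from 231 ± 53.8 (SD, n = 3) to 45.6 ± 5.25 (SD, n = 3), a log2 difference of -1.87 (paired adjusted p = 0.0294). Ezh2, given above, was another. Tcf25, the integrin gene Itgb4 and the cytochrome b5 gene Cyb5a fell with log2 differences of -1.31, -1.12 and -0.87. Their paired adjusted p lay between 0.0294 and 0.0429. A second probe set of Tcf25 showed -0.61 and did not pass. The other 7 did not pass in either fit. They were chosen without overlap, so each of these probe sets was bound to be lower in all 3 pairs. The log2 difference was -1.57 for the calcium pump gene Atp2a1, -0.99 for Syngr2, -0.91 for Taf1c and -0.90 for Sit1, a signalling adaptor of T cells. It was -0.85 for Anks3, -0.83 for A530040E14Rik and -0.72 for the retinal reductase gene Dhrs3. Another probe set of Atp2a1 showed -0.25 and was higher in the Thy pair (0.36).

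The number of calls changed when single arrays were left out. The unpaired fit called 0 probe sets higher without replicate 3 of either group, 1 without double mutant replicate 2 and 6 without RAG1-deficient replicate 1. Leaving out 1 array there leaves its title style in 1 group only, so differences between title styles enter the comparison. The paired fit called 12 higher and 2 lower without the numbered pair, 127 and 64 without the Rag pair, and 3 and 0 without the Thy pair. With 2 arrays left in each group, these 3 paired fits take their spread largely from pooling over probe sets.

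Among 18 tested Polycomb group genes, Bmi1 and Ezh2 moved in opposite directions. Bmi1, a core member of Polycomb repressive complex 1, rose from 1176 ± 550 (SD, n = 3) to 2972 ± 601 (SD, n = 3) in the paired limma fit, a log2 difference of 1.40 ± 0.33 (SE) with an adjusted p of 0.0192. Adjusted over the list alone, 1 member rose (Bmi1) and 1 fell (Ezh2) in the unpaired fit, where 0 passed over all genes. In the paired fit 1 rose and 1 fell over all genes, and Cbx2, with a log2 difference of 0.68 ± 0.23 (SE), rose as well when adjusted over the list alone. A second probe set of Cbx2 gave -0.10. Jarid2 had a log2 difference of -0.35 ± 0.25 (SE) and did not pass. As a group the list did not pass (mean log2 difference 0.07, camera adjusted p = 0.621).

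Developmental regulators that carry H3K27me3 in many cell types were mostly dim in both groups. Of 60 on the array, 15 were bright enough to test, and of these 3 lay above and 12 below 0. None passed over all genes or adjusted over the list alone in either fit. The list's mean log2 difference was -0.18 (camera adjusted p = 0.235). It passed as lower without RAG1-deficient replicate 2 (mean -0.41, adjusted p = 0.0185), and without replicate 1 of that group the mean was 0.0229. The members with the smallest p were Gata4 with a log2 difference of 0.48 ± 0.31 (SE), Tbx2 with -0.70 ± 0.50 (SE), Six2 with -0.57 ± 0.51 (SE) and Hoxa2 with -0.44 ± 0.36 (SE). Outside the naming rule and chosen after its values were seen, Hoxa7 lay under the filter and was not tested, at intensities of 225, 185 and 38.0 in the double mutant against 25.4, 33.6 and 31.2 in the RAG1-deficient arrays.

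Cell cycle genes lay higher in the double mutant as a group. Of 39 tested, 35 were above 0 and 4 below, with a mean log2 difference of 0.33 and a camera adjusted p of 7.6e-09 (7.5e-11 in the paired fit). This call did not hold with an estimated correlation (adjusted p = 0.551 with an estimated correlation, and 0.811 in the paired fit). The mean was 0.20 without RAG1-deficient replicate 2 and 0.21 without double mutant replicate 3. With all arrays it was above 0 in each pair, at 0.13 in the numbered, 0.33 in the Rag and 0.53 in the Thy pair. No single member passed over all genes in either fit. Over the list alone, 0 passed in the unpaired fit and 7 rose in the paired fit. Among these were the DNA replication genes Cdt1, Mcm3 and Cdc45, with log2 differences of 0.73 ± 0.23 (SE), 0.52 ± 0.21 (SE) and 0.67 ± 0.29 (SE). Other probe sets of Cdt1 and Mcm3 showed 0.18 and 0.45 and did not pass over all genes, and that of Cdt1 was at -0.03 in the Rag pair. E2f1, a transcription factor of the G1/S transition, had a log2 difference of 0.75 ± 0.30 (SE) and did not pass over all genes in either fit. That probe set was not the one adjusted over the list alone. The brighter probe set of E2f1, which was, showed 0.44 and did not pass in either way.

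The 12 tested genes of the CDK inhibitor and p53 list did not pass as a group (mean log2 difference -0.001, camera adjusted p = 0.981). Btg2, an antiproliferative p53 target that is also an immediate early gene, fell from 5550 ± 1325 (SD, n = 3) to 3230 ± 766 (SD, n = 3) in the paired limma fit (log2 difference -0.78, adjusted p = 0.0328). With adjustment over the list alone, 0 members passed in the unpaired fit. In the paired fit Cdkn2c (log2 difference 0.50 ± 0.35 SE) and Ccng1 (0.69 ± 0.22 SE) rose and Btg2 fell. Plk2 had a log2 difference of 0.61 ± 0.39 (SE) and did not pass. Outside the naming rule and chosen after its values were seen, Cdkn2a, a tumour suppressor known as a Polycomb target, lay under the filter and was not tested, at 54.8, 65.6 and 267 in the double mutant against 106, 43.5 and 52.2 in the RAG1-deficient arrays.

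Of 32 tested genes of the early thymocyte program, 22 were below 0 and 10 above, with a mean log2 difference of -0.10. The mean was -0.0017 in the numbered, -0.18 in the Rag and -0.13 in the Thy pair, and 0.012 without double mutant replicate 2. The list did not pass in the unpaired fit (camera adjusted p = 0.0798) and passed in the paired fit (0.0205). The paired call did not hold with an estimated correlation (adjusted p = 0.811 with an estimated correlation) or without the Rag pair (adjusted p = 0.054). No early thymocyte gene passed over all genes. Adjusted over the list alone, 0 passed in the unpaired fit, and in the paired fit 3 fell and 1 rose. The falls were Ptcra, the pre-T cell receptor alpha chain, from 8377 ± 1965 (SD, n = 3) to 5239 ± 681 (SD, n = 3), the ETS factor Spib with a log2 difference of -1.08 ± 0.36 (SE), and Rag1. The rise was Lyl1, a bHLH factor of early progenitors, with a log2 difference of 1.06 ± 0.25 (SE). Other probe sets of Spib, Lyl1 and Rag1 showed -0.76, 0.62 and -0.29 and did not pass over all genes.

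Genes of beta-selection and the double-positive stage did not pass as a group (20 tested, mean log2 difference -0.17, camera adjusted p = 0.142). The list passed as lower without RAG1-deficient replicate 2 (mean -0.35, adjusted p = 0.0228) and in the paired fit without the Rag pair (-0.27, adjusted p = 0.00556), and its mean was -0.0262 without RAG1-deficient replicate 1. None passed over all genes. Adjusted over the list alone, 0 passed in the unpaired fit and 1, Cd4, fell in the paired fit with a log2 difference of -1.13 ± 0.63 (SE). Ccr9 (-0.82 ± 0.39 SE), Cd28 (-0.58 ± 0.37 SE) and Cd6 (0.39 ± 0.27 SE) did not pass, and another probe set of Cd6 showed -0.28. On RAG1-deficient replicate 1 alone, the CD8 genes Cd8a and Cd8b1 stood at 2973 and 8426, against at most 81.3 and 164 on the other 5 arrays. Cd4 stood at 699 there, against at most 273 elsewhere. Without that array the unpaired fit called 6 probe sets higher and 0 lower.

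Genes of T cell receptor signalling and the actin cytoskeleton went both ways (36 tested, 17 above and 19 below 0, mean log2 difference -0.01, camera adjusted p = 0.881). None passed in either fit over all genes or adjusted over the list alone. The signalling genes Vav1 and Zap70 had log2 differences of -1.09 ± 0.50 (SE) and -0.71 ± 0.42 (SE), though 2 brighter probe sets of Vav1 showed -0.17 and -0.13. The actin genes Arpc5 and Coro1a had 0.37 ± 0.22 (SE) and -0.35 ± 0.20 (SE). The gamma-delta list (5 tested, camera adjusted p = 0.981) included Trgv4, at 27139 ± 5428 (SD, n = 3) in the RAG1-deficient and 28229 ± 4871 (SD, n = 3) in the double mutant arrays. None of its members passed, with Icos at 0.46 ± 0.48 (SE), Blk at -0.47 ± 0.49 (SE) and Sox13 at 0.05 ± 0.22 (SE) on the log2 scale.

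The granzyme genes Gzma and Gzmb, cytotoxic proteases of NK and other killer cells, rose in the paired limma fit. Gzma went from 2068 ± 780 (SD, n = 3) to 7008 ± 1756 (SD, n = 3) and Gzmb from 230 ± 59.9 (SD, n = 3) to 623 ± 252 (SD, n = 3), with log2 differences of 1.79 and 1.31 and paired adjusted p of 0.00356 and 0.0261. Both rose in the unpaired and in the paired fit when adjusted over the list alone, and no other of the 17 tested NK and innate lymphoid genes passed, with Zbtb16 at 1.36 ± 0.68 (SE) and Ncr1 at 0.45 ± 0.28 (SE) on the log2 scale. Over all genes 0 passed in the unpaired fit. The list passed in the unpaired fit (mean log2 difference 0.33, camera adjusted p = 0.0355), but not in the paired fit (0.0613) nor with an estimated correlation (adjusted p = 0.642 with an estimated correlation). The mean was 0.34 in the numbered, -0.09 in the Rag and 0.73 in the Thy pair. The list's adjusted p was 0.101 and 0.182 without RAG1-deficient replicates 1 and 3, and 0.141 and 0.181 without double mutant replicates 1 and 3.

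Markers of antigen-presenting and dendritic cells lay lower in the double mutant. Of 14 tested, 12 were below 0, with a mean log2 difference of -0.35 and a camera adjusted p of 0.0203 (5.1e-04 in the paired fit), though not with an estimated correlation (adjusted p = 0.782 with an estimated correlation). The mean was -0.27 in the numbered, -0.66 in the Rag and -0.13 in the Thy pair, and lay between -0.76 and -0.0574 with 1 array left out. No antigen-presenting gene passed over all genes. Adjusted over the list alone, 0 passed in the unpaired fit and 1, H2-DMb1 with a log2 difference of -0.77 ± 0.39 (SE), fell in the paired fit. Ccl22 (-0.42 ± 0.28 SE), Ciita (-0.41 ± 0.33 SE) and Itgax (-0.36 ± 0.23 SE) did not pass. The list's adjusted p was 0.522 without RAG1-deficient replicate 1, 0.103 without its replicate 2, and 0.0908 and 0.379 without double mutant replicates 2 and 3. In the paired fit without the Rag pair it was 0.054.

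Myeloid and granulocyte markers followed a single pair of arrays. Their mean log2 difference over 20 tested genes was -1.35 in the Rag pair but 0.50 in the numbered and 0.45 in the Thy pair, with a mean of -0.14 over the pairs. The list did not pass in the unpaired fit (camera adjusted p = 0.0798) and passed as lower in the paired fit (0.0327). In the unpaired fit it passed as lower without double mutant replicate 1 (adjusted p = 2.4e-04) and without RAG1-deficient replicate 3 (5.0e-05). Without the Rag pair the paired fit gave it as higher, with a mean of 0.47 and an adjusted p of 2.2e-05. The paired call did not hold with an estimated correlation (adjusted p = 0.816 with an estimated correlation). No myeloid gene passed in either fit over all genes or adjusted over the list alone, among them Ccr2 (-0.88 ± 0.30 SE), Tyrobp (-0.62 ± 0.43 SE), Lyz2 (-0.51 ± 0.35 SE) and Cd14 (-0.42 ± 0.28 SE). The Rag arrays also stood apart in the 3' beta-actin control, at 4448 and 5826 against 23267 to 38661 on the other 4.

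B lineage markers did not pass as a list (9 tested, 8 below 0, mean log2 difference -0.27, camera adjusted p = 0.0798). They passed as lower without RAG1-deficient replicate 3 (mean -0.40, adjusted p = 0.00498) and with the mean of all probe sets of a gene (0.0466), and the mean was 0.11 in the Thy pair. None passed in either fit over all genes or adjusted over the list alone, with Pax5 at -0.85 ± 0.48 (SE), Ighm at -0.41 ± 0.28 (SE) and Vpreb1 at -0.40 ± 0.29 (SE) on the log2 scale. Erythroid and platelet markers did not pass either (10 tested, 7 above 0, mean 0.32, camera adjusted p = 0.0798). The erythroid mean was 0.52 in the numbered, -0.20 in the Rag and 0.63 in the Thy pair. The list passed without RAG1-deficient replicate 2 (mean 0.62, adjusted p = 0.0228), with array weights (0.0418) and in the paired fit without the Rag pair (5.0e-05), and without RAG1-deficient replicate 3 its mean was -0.13. Over all genes 0 of them passed in either fit. Adjusted over the list alone, 0 rose in the unpaired fit and 3 in the paired fit: the transcription factor gene Nfe2 (0.96 ± 0.29 SE), the carbonic anhydrase gene Car2 (0.86 ± 0.30 SE) and the erythropoietin receptor gene Epor, from 73.5 ± 43.4 (SD, n = 3) to 165 ± 24.0 (SD, n = 3). Among 15 tested stromal markers (mean -0.07, camera adjusted p = 0.876), the growth factor receptor gene Pdgfrb rose in the paired limma fit from 182 ± 41.0 (SD, n = 3) to 454 ± 72.1 (SD, n = 3), with an adjusted p of 0.0436. It rose in both fits when adjusted over the list alone. Fn1 (-0.54 ± 0.43 SE), Dcn (-0.60 ± 0.71 SE) and Epcam (-0.24 ± 0.35 SE) did not pass.

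**Figure D2:**
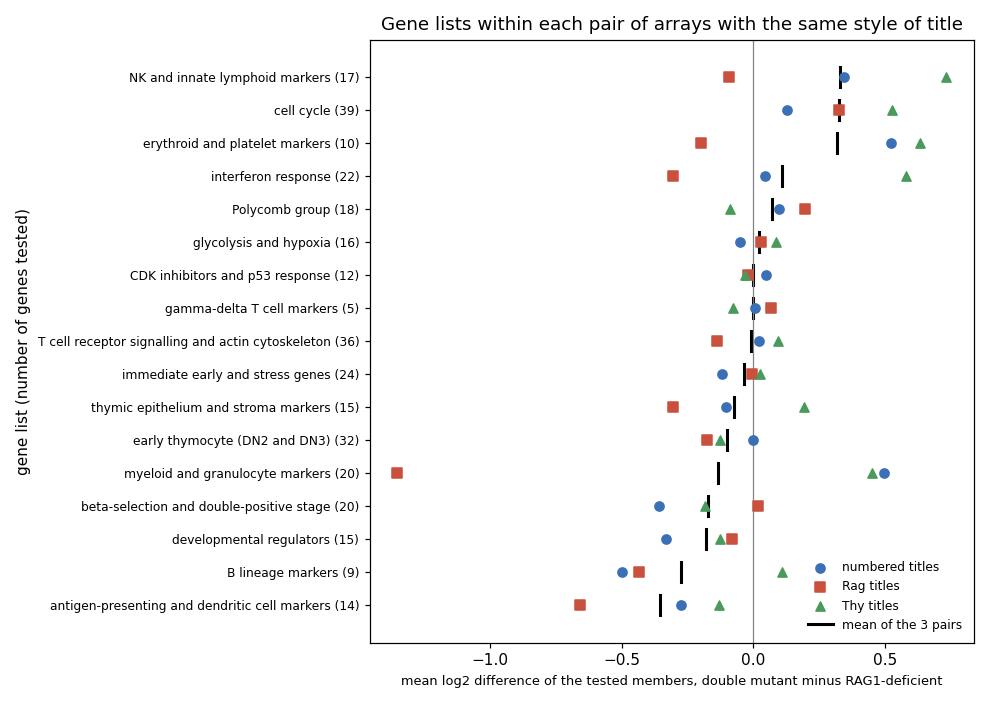
Mean log2 difference, double mutant minus RAG1-deficient, of the tested members of each fixed gene list within each pair of arrays whose titles share a style (marker shape and colour), with the mean of the 3 pairs as a black bar and the number of genes tested in brackets. Cell cycle genes lie above 0 in all 3 pairs (0.13, 0.33 and 0.53), antigen-presenting markers below 0 in all 3, and myeloid markers at -1.35 in the Rag pair against 0.50 and 0.45.

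The remaining lists did not pass in either fit with all arrays. Immediate early and stress genes (24 tested, mean -0.03 but median 0.07, camera adjusted p = 0.71) held 1 member that fell in the paired fit, Btg2, also when adjusted over the list alone. Klf4 (-0.86 ± 0.41 SE), Zfp36 (-0.66 ± 0.40 SE) and Ppp1r15a (-0.59 ± 0.35 SE) did not pass. Interferon response genes (22 tested, 18 above 0, mean 0.11, camera adjusted p = 0.319) had 0 members passing in any of these ways, with Iigp1 at 0.39 ± 0.24 (SE), Tap1 at 0.41 ± 0.26 (SE) and Ifi204 at -0.72 ± 0.47 (SE). The interferon mean was 0.05 in the numbered, -0.30 in the Rag and 0.58 in the Thy pair. The list passed as higher without RAG1-deficient replicate 2 (mean 0.22, adjusted p = 0.0326), with array weights (0.0337) and in the paired fit without the Rag pair (0.0013), and its mean was -0.15 without RAG1-deficient replicate 3. No member passed either among glycolysis and hypoxia genes (16 tested, mean 0.02, camera adjusted p = 0.881), with Pgam1 at 0.35 ± 0.21 (SE) and Aldoa at -0.29 ± 0.22 (SE). Of the sex-linked genes only Xist was bright enough to test, at 5230 ± 4347 (SD, n = 3) against 2689 ± 1384 (SD, n = 3), and did not pass (log2 difference -0.49 ± 0.81 SE). Its list was too short for a list test.

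The exact test, which takes no account of the pairs, detected no difference in RNA quality between the groups. In this design it cannot reach a p under 0.1. The log2 difference between the 3' and 5' control probe sets of Gapdh was 0.11 ± 0.30 (SD, n = 3) in the RAG1-deficient and -0.06 ± 0.23 (SD, n = 3) in the double mutant arrays (exact permutation p = 0.6), and that of beta-actin 0.86 ± 0.35 (SD, n = 3) and 0.92 ± 0.58 (SD, n = 3) (exact permutation p = 0.9). Within each pair the Gapdh value was lower in the double mutant. It was -0.107 against 0.0597 in the numbered, 0.185 against 0.429 in the Rag and -0.259 against -0.169 in the Thy pair. The beta-actin value was higher in the double mutant in the numbered and Rag pairs and lower in the Thy pair. RAG1-deficient replicate 3 carried an 18S ribosomal RNA signal of 18830 at the 5' control probe set, against 146 to 334 on the other 5 arrays.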

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

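The paired fits joined with another setting, and those without a pair, were chosen after the data had been seen. Bex4, Bex1 and Mt2 were called under each of the 11 alternatives of scaling, pseudocount, floor, filter, variance model, weights and pairing, and the median log2 difference of all tested probe sets lay between -0.0491 and 0.0414 under these and without each array. The unpaired count of higher probe sets was 5 with quantile scaling, 6 with the filter at the 60th percentile, 6 with array weights and 9 at an adjusted p under 0.1. The title-style block raised it to 43, with 8 lower, and leaving out each array gave 0 to 6. With the block, Ezh2 passed at its log2 difference of -1.60, and under no alternative of the unpaired fit (its adjusted p there lay between 0.232 and 0.889). Its paired call held in 6 of 10 paired alternatives and ended with quantile scaling, without the filter, without the numbered pair and without the Thy pair, with adjusted p of 3.7e-09 to 0.111 over the 10. The lowest came without the Rag pair, with 2 arrays left in each group and a spread largely pooled over probe sets. Higher and lower counts with the block were 76 and 29 at an adjusted p under 0.1, 21 and 1 with quantile scaling, 5 and 0 without the filter, 12 and 2 without the numbered pair, 127 and 64 without the Rag pair, and 3 and 0 without the Thy pair. A fold of at least 2 left 5 lower, median centring 3 lower, and a pseudocount of 1 left 24 higher. The cause of these moves was not tested. Of the 51 probe sets called with the block, quantile scaling shared 22 of its 22 calls, cyclic loess 38 of 38, median centring 38 of 38, and the fit without the Rag pair 50 of 191.

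Values for lists are mean log2 differences. Without the filter the antigen-presenting (-0.33) and NK (0.25) calls ended, and with array weights the antigen-presenting call ended (-0.13) while erythroid (0.55) and interferon (0.26) lists passed. The early thymocyte list passed with the filter at the 60th percentile (-0.12), and the B lineage list with the mean of all probe sets (-0.28). With the block the early thymocyte (-0.10) and myeloid (-0.14) lists passed and the NK list (0.33) did not. The cell cycle (0.33), antigen-presenting (-0.35) and NK (0.33) calls of the unpaired fit ended with an estimated correlation. Fry, which tests a list against no change and not against other genes, called none of these lists. With the block and an estimated correlation none of the 17 tested lists passed, the early thymocyte and myeloid lists included. With the block and without the Rag pair, the myeloid list reversed (0.47), the beta-selection (-0.27), erythroid (0.58) and interferon (0.31) lists passed, and the antigen-presenting list did not (-0.20). Leaving out each array gave ranges of -0.41 to 0.0229 for the developmental regulators, -0.35 to -0.0262 for beta-selection, -0.40 to -0.18 for B lineage, -0.48 to 0.19 for myeloid, -0.76 to -0.0574 for antigen-presenting, 0.23 to 0.51 for NK, -0.13 to 0.62 for erythroid and -0.15 to 0.25 for interferon genes, and each of these lists gained or lost its call without at least 1 array. Where a group is left with 2 arrays, the spread is pooled by limma. These fits are unpaired, so leaving out 1 array leaves its title style in 1 group only. The moves therefore mix single arrays with differences between title styles. The early thymocyte list ranged from -0.18 to 0.012 and did not pass without any array. The cell cycle list passed without each array, with means of 0.20 to 0.45 and adjusted p between 9.0e-11 and 0.00207. Its camera adjusted p over all alternatives, the paired ones included, lay between 7.5e-11 and 0.811, and its fry adjusted p was 0.865. The cause of these changes was not tested.

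Of 582 values of named genes with 1 array left out, 15 had another sign, in 6 results. The filter, a percentile of the intensities and no measure of background, limits the tests to 7642 of 12422 probe sets.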

Other observations

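The NK cell test below was chosen after its result had been seen, as were the limit on dim genes in the mast cell test, the paired fits without a pair, the genes named in this part and the values of single arrays.

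More genes passed in the paired limma fit than the naming rule covers. Pbx3, a homeobox gene, rose from 55.7 ± 45.9 (SD, n = 3) to 413 ± 144 (SD, n = 3), a log2 difference of 2.67, and its 2 other probe sets, at 1.39 and 1.68, did not pass. Zmat3, a p53 target, rose by 2.31, the actin regulator Enah by 2.61, the stem cell antigen gene Prom1 by 2.05 and the cathepsin gene Ctsf by 2.23. Gkap1 rose by 2.92 at 1 probe set, while another showed -0.24 and did not pass. Mt1, the neighbour and relative of Mt2, rose by 1.76 (paired adjusted p = 0.0436). Epop, which binds Polycomb repressive complex 2, rose by 1.92, and both probe sets of the cytochrome oxidase gene Cox6b2 rose, by 1.58 and 1.37, with overlap between the groups. Cst7, an inhibitor of proteases in killer cells, rose by 1.40. Ifi30 fell with a log2 difference of -1.19 and Tmem50b with -0.84, each lower in all 3 pairs but with overlap between the groups.

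The excess of rises over falls in the paired fit (43 against 8) was weighed against scaling and against DNA of another strain around Ezh2. With quantile, cyclic loess or median scaling the share of rises among the calls lay between 84.2% and 95.5%, while the calls went from 51 to between 22 and 38. This argues against array offsets or trends with intensity that these scalings remove as its source. All of them set the arrays to a common level, so a change shared by most transcripts stays open. Counted at the brightest probe set of each gene, which leaves out Basp1, 47 genes other than Ezh2 were called. Of these, 0% lay among the 80 tested genes nearest to Ezh2, which argues against linked strain DNA as the source of most calls. In the paired fit 18.8% of those neighbours and 13.6% of other genes had an unadjusted p under 0.05 (Fisher's exact p = 0.19). Weaker effects of linked DNA stay open, and strain DNA elsewhere in the genome was not tested. The share of rises was 66.5% without the Rag pair, so its size depends on that pair. Of the 4 splits that part all 3 pairs, the real one called 51 probe sets and the highest other 1, so 1 of 4 called as many, and 4 splits are too few for a share under 0.05.

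In the unpaired fit the real split called 3 probe sets higher, the highest of the others called 1, and 1 of the 10 splits called as many. For probe sets called lower the real split and the highest other gave 0, so all 10 splits gave as many. The real split called 3 lists and the highest other 6, and 4 of the 10 splits called at least as many. With 10 splits no share can lie under 0.05.

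Gzma and Gzmb may reflect a larger share of NK or innate lymphoid cells. The other 15 tested members of that list had a median log2 difference of 0.146 with an interquartile range of 0.569, 9 of them above 0, against 1.31 for Gzmb. Among the bright members, Id2, which early thymocytes may also carry, went from 1830 to 2084. The NK receptor genes Klrd1, Klrc1 and Klra7 went from 645 to 498, from 302 to 263 and from 223 to 217, and Il18r1 from 356 to 291. Ncr1 went from 305 to 426, Klrk1 from 218 to 299 and Xcl1 from 519 to 730. None of these passed. Ccl5 gives no direction, since RAG1-deficient replicate 2 alone read 7620, with 1602 and 867 on the other RAG1-deficient arrays and 1681, 2727 and 1599 on the double mutant arrays. This spread leaves a larger share and a change within the thymocytes unable to be told apart, and the sources used here name no sort that would remove NK cells.

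Mast cells or basophils were weighed as another source, because the mast cell protease gene Cpa3 rose from 413 ± 224 (SD, n = 3) to 1762 ± 1074 (SD, n = 3), a log2 difference of 2.05. The 4 other tested members of that list (Cma1, Tpsb2, Kit and Gata2), of which Kit is also made by early thymocytes, had a median of 0.181 with an interquartile range of 0.237. Of these 4, only Kit lay above the highest array median in the RAG1-deficient cells. The median lies below the bound set in advance, but that bound took no account of dim members, so mast cells stay open.

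For Bex1 and Bex4, a change shared by neighbouring genes of the X chromosome was tested. The 4 tested neighbours (Gprasp1, Tceal9, Morf4l2 and Slc25a53) had a median log2 difference of 0.0610 with an interquartile range of 0.190. This argues against a change shared by these 4. Their mean intensities in the RAG1-deficient arrays were 162, 2552, 3700 and 325, so they do not speak for neighbours that are silent there. Neighbours without a tested probe set were not examined. No other biological explanation of the rise of Bex1 and Bex4 was tested.

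Single arrays of the RAG1-deficient group stood apart. On replicate 1 alone, the T cell receptor alpha segment Trav9d-3 read 1723 at 1 probe set, with at most 260 on the other 5 arrays, and 335 at another, with at most 26.9, beside the CD8 genes given above. The homeobox gene Dlx1 read 262 there, with at most 10.3 elsewhere. On replicate 2 alone, the interferon-inducible gene Ifi202b read 552 with at most 21.3 elsewhere. The neutrophil genes S100a8, S100a9, Ngp, Camp and Lcn2 read 4809, 3706, 2237, 3912 and 506 there, with at most 1524, 1128, 790, 1403 and 184 elsewhere. Whether these 2 arrays hold what their labels say was not tested. The CD8 and Trav9d-3 signal leaves the RAG1-deficient label or the content of replicate 1 in doubt. Its title ends in WT, but so does that of replicate 3, which read 14.7 for Cd8a and 45.3 for Cd8b1. The ending therefore does not go with the CD8 signal. Replicate 2 read 79.6 for Cd8a and 164 for Cd8b1, and its neutrophil genes and Ifi202b do not bear on Rag1. What the sample of replicate 2 held stays open, and the control means that rest on both arrays stay in doubt. Counting probe sets more than 2 log2 units above the next array gave 6 on replicate 1, 1 on replicate 2, 1 on replicate 3 and 0 on each double mutant array.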
